A study of Mus musculus with 16 samples.

How the data were processed

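The deposited table holds, per the labels, signal values that the authors made with DESeq2, read counts per gene divided by a size factor per library, for 30199 genes and 16 libraries. Upstream of it the authors trimmed reads with Trimmomatic 0.36 and aligned them with STAR 2.6.0c to GRCm38, and normalized them with DESeq2 1.28.1. The gene counting program, the annotation release and the mouse strain are not given in the sources used here. Libraries were made from a piece of frozen liver by oligo(dT) selection, and no strand marking is stated, so overlapping genes on opposite strands are uncertain. For every library all values were whole multiples of 1 step to a tolerance of 1e-04, and dividing by the step gave whole reads. For Tip30+/- 2 the size factor read from the step was near 1, at 0.996, and 100% of its values were whole multiples as well. Of the table's genes, 18821 carry a symbol in it, 11328 were named from a gene table and 50 are known by identifier only, and positions come from GENCODE M21. No 2 libraries were copies of each other, with a lowest chi-square per gene of 23.4 between any pair. Mitochondrial genes took 3.42% to 5.80% of reads.

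The comparisons, the gene lists, the named-gene rule and the alternative settings were fixed before the data were examined, from the labels alone. Settings chosen after seeing the data were 3: leaving out the 4 libraries low in Zhx2, Zhx2 as a covariate, and Pklr as a covariate for Hcn3. Genes with a mean of at least 10 normalized counts over all libraries were tested, with Ncoa5, Htatip2 and Hcn3 always kept, 15263 in all. The test was limma (trend and robust) on log2 of the value plus 1, as 1 linear model of 4 group means over 16 libraries, 2-sided, with Benjamini-Hochberg adjustment over all genes within each comparison. Adjusted p values without another tool's name are from this limma fit, and a gene passed at an adjusted p below 0.05. The interaction is the double heterozygote minus both single heterozygotes plus wild type. Folds are powers of 2 of the fitted log2 change. For Ncoa5, Htatip2, Hcn3 and Pklr a 2-sided exact permutation test over the 70 arrangements of 8 mice was added. Groups were called not overlapping when every mouse of 1 group lay above every mouse of the other. The share of such genes given for chance is a mean over all arrangements of 8 mice. Genes vary together, so single arrangements can lie far from that mean, and an excess over it was not tested.

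Genes named in the text follow a rule: an adjusted p under 0.05, a mean of at least 50 in the higher group and groups that do not overlap, and of these the 12 with the largest rise and the 12 with the largest fall. Predicted genes were left out, except where fewer than 10 genes passed, when all were named together with the 6 of smallest p as values. Ncoa5, Htatip2 and Hcn3 are named in every comparison with wild type. From each called list up to 4 members that passed are named, or else 2 as values.

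There were 37 gene lists with 751 members written down from general knowledge, of which 680 were tested. Lists were tested by camera in limma with a preset correlation of 0.01 between genes, by camera with an estimated correlation and by fry, each adjusted over the 37 lists within a comparison. Counts of members adjusted over the list alone use the p values of that list only. The preset correlation is low for genes that vary together, so a call lost with an estimated correlation is weak. List means per library average the log2 values of members after subtracting the wild-type mean.

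The chain was tested on simulated data made with 200 changed genes among 15263, in 5 draws. Changed genes were drawn among those with a mean of at least 50, so the recovery rates do not cover genes below that. For double heterozygotes against wild type limma recovered 28.1%, 77.9% and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold, and 5.06% of its calls were false. For the interaction it recovered 8.36% of 1.5-fold changes. A list raised in every draw was called in 5 of 5 draws, and 0 of 185 tests of unchanged lists were called. Each gene was drawn independently and unchanged lists held random genes, so this tests neither gene calls nor list calls where genes vary together. The share of false calls in the real libraries may therefore differ. Alternatives covered DESeq2, edgeR and limma-voom on the recovered reads, pseudocounts of 0.5 and 5, no filter and a filter at 50, upper-quartile and TMM scaling, sample weights, variance moderation that is not robust, a mouse tag covariate (under 4300 or not), the 2 groups alone, and each mouse left out. In every splitting test the same libraries were divided in all possible balanced ways, 35 per pair of groups, and for the interaction genotype was assigned at random 100 times. Contrasts that share the wild-type mice were set against 100 simulations of unchanged groups, and against the 6 ways to give each contrast its own 2 wild-type mice. In the simulations the residuals of the 16 libraries were dealt at random to 4 groups, and the contrasts shared 1 control group. The first principal component took 26.3% and the second 17.0% of the variance. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and statmod 1.5.0, and Python 3.11.15 with matplotlib 3.10.9. Some single genes that were tested are not reported here.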

Results

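Liver messenger RNA was sequenced from 16 female mice at the age of 5 months, with 1 library per mouse and 4 mice in each of 4 genotypes. The genotypes were wild type, Ncoa5+/-, Tip30+/- and the double heterozygote Ncoa5+/-Tip30+/-. Ncoa5 encodes a coregulator of nuclear receptors, and Tip30 is the common name of Htatip2, a short-chain dehydrogenase studied as a tumour suppressor. Whole reads assigned to genes came to 26058724 to 37939978 per wild-type library and 26262744 to 28895680 per Ncoa5+/- library. They came to 30574997 to 35978055 per Tip30+/- library and 24740706 to 31987259 per Ncoa5+/-Tip30+/- library. Between 21686 and 24142 genes had at least 1 read in a library, and 15263 genes were tested. Fold changes below compare n = 4 mice per group, except within ranges of mouse tags and in fits that leave out mice, errors are SE on the log2 scale unless another error is named, and adjusted p values come from limma.

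Htatip2 (ENSMUSG00000039745, GRCm38 chromosome 7, 49759115 to 49773975) was lower in all mice labelled with the Tip30 deletion than in all mice without it. It fell by 1.41 ± 0.13 in Tip30+/- livers, to 37.7% of wild type (95% confidence interval of the log2 change -1.68 to -1.14, adjusted p = 5.88e-05). In Ncoa5+/-Tip30+/- livers it fell by 1.08 ± 0.13, to 47.4% of wild type (adjusted p = 0.000231). Mice labelled Ncoa5+/- held Htatip2 at 119% of wild type (log2 0.25 ± 0.13, adjusted p = 0.535). Ncoa5 (ENSMUSG00000039804, chromosome 2, 165000357 to 165034867) stood at 381 ± 35.1 normalized counts (SD) in mice labelled Ncoa5+/- and 426 ± 42.1 in wild type. This was 89.5% of wild type, a log2 change of -0.16 ± 0.10 (95% confidence interval -0.38 to 0.06, adjusted p = 0.658, two-sided exact permutation p = 0.171). The double heterozygotes stood at 92.1% of the wild-type Ncoa5 level (exact permutation p = 0.257) and Tip30+/- mice at 96.1%. The Ncoa5 reads therefore do not check the Ncoa5 genotype, which rests on the labels alone, and which part of the gene was deleted is not given in the sources used here.

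Hcn3, a hyperpolarization-activated ion channel gene and the subject of the series title, was higher than wild type in all 12 heterozygous livers. Wild-type livers held 349 ± 95.7 normalized counts (SD, n = 4), livers labelled Ncoa5+/- 795 ± 268, Tip30+/- livers 1137 ± 73.8 and double heterozygotes 1788 ± 376. Against wild type, Hcn3 rose 2.24-fold in mice labelled Ncoa5+/- (log2 1.16 ± 0.23, adjusted p = 0.0313) and 3.34-fold in Tip30+/- mice (log2 1.74 ± 0.23, adjusted p = 0.0099). In double heterozygotes it rose 5.17-fold (log2 2.37 ± 0.23, adjusted p = 7.82e-05). Each of these 3 contrasts gave an exact permutation p of 0.0286, the smallest that 70 arrangements of 8 mice allow. The double heterozygotes lay 2.31-fold above Ncoa5+/- (adjusted p = 0.174) and 1.55-fold above Tip30+/- (adjusted p = 0.125), and neither difference passed over all genes, although each gave an exact permutation p of 0.0286. On the log2 scale the double heterozygotes differed from the sum of both single effects by -0.53 ± 0.33 (95% confidence interval -1.23 to 0.16, unadjusted p = 0.124 by limma), so neither addition nor a departure from it is shown. Within the range of lower and that of higher mouse tags, divided at 4300, the log2 difference from wild type was 1.35 and 0.97 (± 0.39) for Ncoa5+/- and at least 2.14 ± 0.39 for the double heterozygotes (2 mice against 2 in each range). For Tip30+/- it was 1.78 ± 0.36 in the lower range (3 mice against 2), and the upper range holds a single Tip30+/- mouse.

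**Figure D1:**
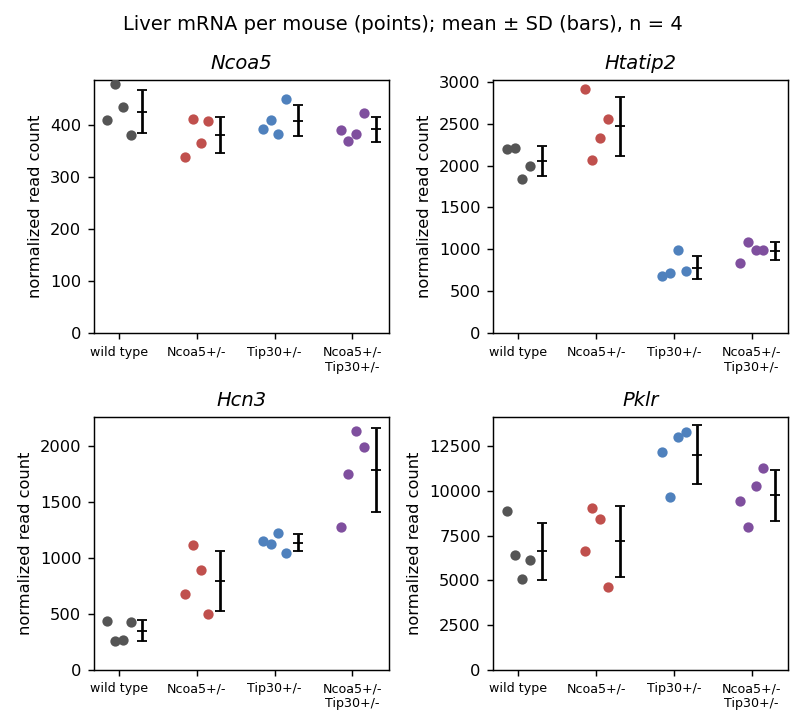
Normalized counts of Ncoa5, Htatip2, Hcn3 and Pklr in each liver, by genotype, on linear axes from 0; points are mice, lines are group means and bars are ± SD (n = 4). Hcn3 ran from 262 to 440 in wild type, 498 to 1117 in mice labelled Ncoa5+/-, 1047 to 1224 in Tip30+/- and 1275 to 2134 in double heterozygotes.

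The Hcn3 gene (ENSMUSG00000028051, chromosome 3, 89146074 to 89160196, minus strand) overlaps the liver pyruvate kinase gene Pklr (ENSMUSG00000041237, 89136142 to 89146784, plus strand). The last 711 exon bases of Hcn3, 17.1% of its 4154, lie in a Pklr exon, and since the library labels state no strand marking, reads there could come from either gene. Pklr stood at 6622 normalized counts in wild type and 12026 in Tip30+/- (log2 0.88 ± 0.20, adjusted p = 0.243, exact permutation p = 0.0286). Pklr differed from wild type by log2 0.57 ± 0.20 in double heterozygotes (adjusted p = 0.11) and 0.10 ± 0.20 in mice labelled Ncoa5+/- (adjusted p = 0.928). The log2 ratio of Hcn3 to Pklr lay above wild type by 1.07 ± 0.18 in mice labelled Ncoa5+/-, 0.86 ± 0.18 in Tip30+/- and 1.80 ± 0.18 in double heterozygotes. Hcn2, the only other member of the HCN family that was tested, had 14.0 normalized counts in wild type and 25.5 in double heterozygotes (adjusted p = 0.158). Leaving out 1 mouse left Hcn3 called in 8 of 8 fits for the double heterozygotes, 5 of 8 for Tip30+/- and 3 of 8 for Ncoa5+/-. The Tip30+/- call was lost without wild type 2 (adjusted p = 0.0593), Tip30+/- 1 (0.0596) or Tip30+/- 3 (0.0669). The Ncoa5+/- call was lost without wild type 2 (0.0791), wild type 3 (0.105), Ncoa5+/- 1 (0.0638), Ncoa5+/- 2 (0.0816) or Ncoa5+/- 3 (0.0907). Over all settings the adjusted p of Hcn3 ran from 0.000102 to 0.17 for Ncoa5+/-, 1.24e-09 to 0.566 for Tip30+/- and 4.12e-21 to 0.000624 for the double heterozygotes.

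**Figure D2:**
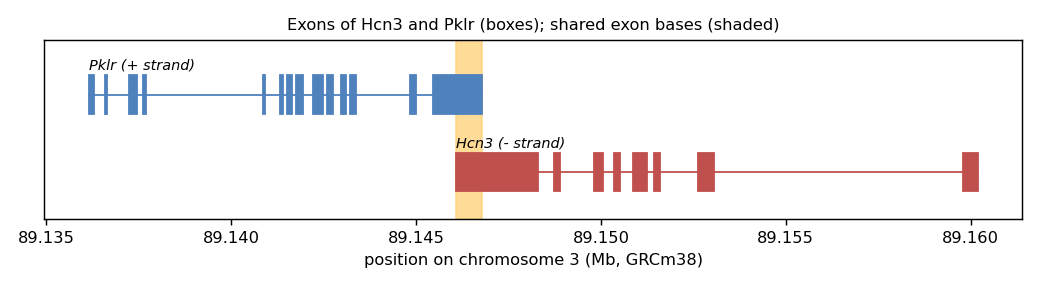
Exons of Pklr (plus strand) and Hcn3 (minus strand) along chromosome 3 of GRCm38, drawn to scale in bases; boxes are merged annotated exons. The shaded stretch, 89146074 to 89146784, is the exon sequence shared by both genes.

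What the loss of 1 Ncoa5 allele changes was asked by comparing mice labelled Ncoa5+/- with wild type. Targets of p53, the stress-activated transcription factor, were the group that stood out: 14 of 21 rose and none fell over all genes, and 16 rose and 1 (Sesn1) fell adjusted over the list alone. Phlda3, a repressor of Akt signalling, rose 34.5-fold (log2 5.11 ± 0.47, adjusted p = 0.000135, with 4371 normalized counts in Ncoa5+/- 1 and 1744 to 1820 in the other 3), and Eda2r, a receptor gene, rose 29.3-fold (4.87 ± 0.46, 5.79e-05). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 22.7-fold (4.51 ± 0.43, 0.000186), and the cyclin gene Ccng1 rose 3.40-fold (1.77 ± 0.20, 0.000214). The other members named by rule were the TRAIL receptor gene Tnfrsf10b (11.4-fold, adjusted p = 0.00037), the stress cytokine gene Gdf15 (6.54-fold, 0.00711) and Psrc1 (21.5-fold, 0.0144). Psrc1 had 1.72 normalized counts in wild type, so its fold is uncertain. The list was called up with an adjusted p of 2.3e-28, and it was the only list still called with an estimated correlation (adjusted p = 0.0203 with an estimated correlation, 3.47e-29 to 0.0203 over all settings). The list mean per liver, on the log2 scale, was 1.22 to 2.31 in the 8 mice labelled with the Ncoa5 deletion and -0.28 to 0.23 in the other 8. Trp53 itself, the gene of p53, did not pass (log2 -0.01, adjusted p = 0.984).

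**Figure D3:**
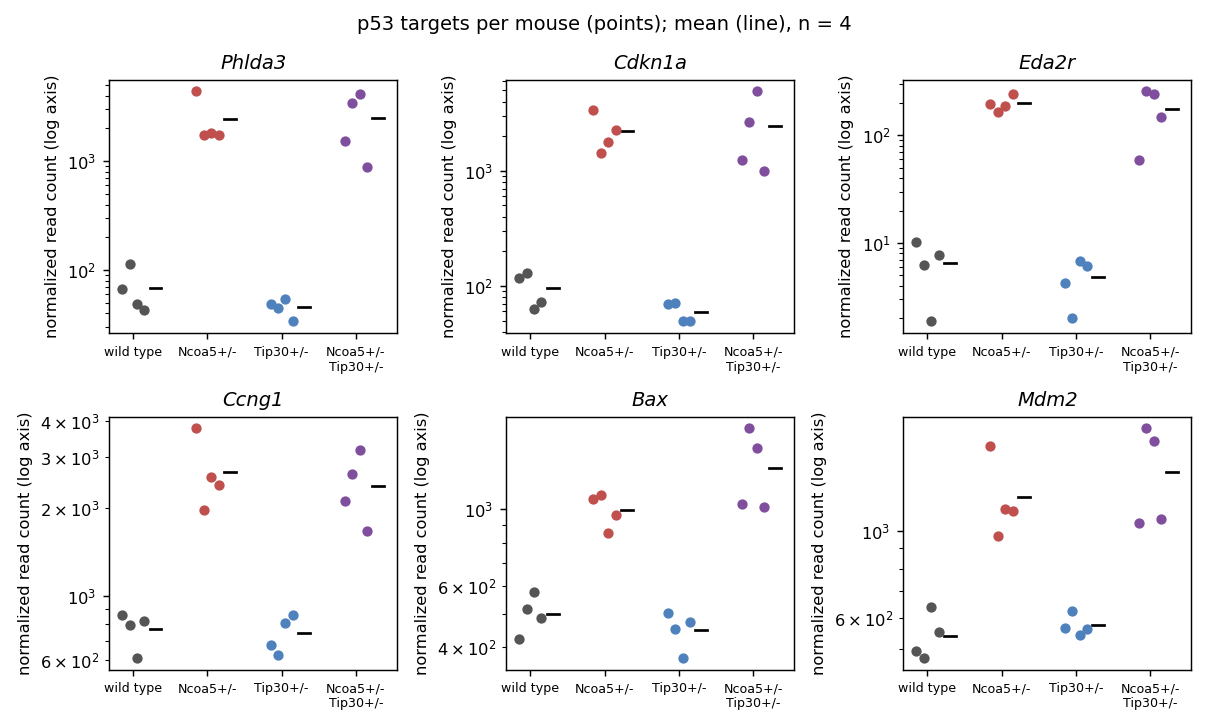
Normalized counts of 6 p53 targets in each liver, by genotype, on log axes; points are mice and lines are group means (n = 4). All 4 Ncoa5+/- livers and all 4 double heterozygotes lay above all wild-type and Tip30+/- livers for each of the 6 genes.

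In all, 85 genes changed in mice labelled Ncoa5+/-, 81 up and 4 down, and 64 and 3 of them by more than 2-fold. Genes named outside the p53 list that rose were the glutamate receptor gene Gria3 (25.7-fold, log2 4.68 ± 0.41, adjusted p = 5.79e-05), the cytokine gene Lif (16.5-fold, 0.0117), Ddit4l (13.7-fold, 0.000186), Fam212b (12.3-fold, 0.000857) and Ddias (7.92-fold, 0.0016). Lif had 2.55 normalized counts in wild type, most of them in wild type 2, so its fold is uncertain. Those that fell were the metalloreductase gene Steap2 (fell by 1.68 ± 0.36, adjusted p = 0.044), the orphan nuclear receptor gene Esrrg (fell by 1.22 ± 0.26, 0.0451) and Hnf4aos (fell by 1.40 ± 0.23, 0.00422). Hnf4aos lies antisense to Hnf4a (log2 -0.28, adjusted p = 0.645), and without strand marking its reads cannot be assigned with certainty. The fourth, the pseudogene Zfp862-ps (fell by 0.57 ± 0.11, 0.0267), falls outside the rule for named genes and was chosen after its values were seen. The number of genes whose groups did not overlap was 866, or 5.67%, where chance gives 2.86% on average. The count was 45 without Ncoa5+/- 1, 47 without wild type 3, 53 without wild type 4, 56 without Ncoa5+/- 4, 257 by DESeq2 (81.3% up), 56 when fitted to these 2 groups alone and 29 without the 4 livers low in Zhx2. Steap2 and Esrrg each lost the call in 6 of 8 fits that left out 1 mouse, at adjusted p up to 0.162 and 0.147, Psrc1 in 4 (up to 0.0707) and Lif without wild type 3 (0.054) or Ncoa5+/- 1 (0.0556). Over all settings the adjusted p reached 0.185 for Lif and 0.255 for Psrc1, and it ran from 2.8e-10 to 0.0796 for Fam212b and from 2.19e-07 to 0.119 for Gdf15, highest without the livers low in Zhx2, and from 3.48e-06 to 0.0515 for Hnf4aos.

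Lists of lymphocytes, cytokines, interferon genes, macrophages, cholangiocytes and matrix were called up in mice labelled Ncoa5+/-, while those of neutrophils (adjusted p = 0.222) and sinusoidal endothelium (0.599) were not. All 6 calls were lost with an estimated correlation (adjusted p = 0.0674 to 0.649). Of 18 lymphocyte markers 2 rose, and 7 adjusted over the list alone: Cd8a, a T cell coreceptor gene, rose 9.18-fold (log2 3.20 ± 0.53, adjusted p = 0.00517) and Nkg7 3.13-fold (1.65 ± 0.29, 0.0117). Of 17 NF-kB and cytokine genes 3 rose, and 6 adjusted over the list alone: the chemokine gene Cxcl9 (log2 1.56 ± 0.28, adjusted p = 0.0138), Relb (0.93 ± 0.18, 0.0267) and Icam1 (0.66 ± 0.13, 0.0267). Of 28 type I interferon genes none passed over all genes and 14 rose adjusted over the list alone, with Irf7 at log2 1.04 (adjusted p = 0.0864) and Bst2 at 0.59 (0.152). The lists of lymphocytes (adjusted p = 5.45e-07), NF-kB (2.21e-07) and interferon genes (1.85e-13) were called up, and these calls were lost with an estimated correlation (adjusted p = 0.306, 0.0674 and 0.306 with an estimated correlation). Markers of macrophages and Kupffer cells were called up too (adjusted p = 5.45e-07, and adjusted p = 0.383 with an estimated correlation), with none of 19 passing and Lyz2 at log2 0.61 (adjusted p = 0.337). The macrophage list mean was 0.45 in wild type 1 and 2, -0.16 and -0.74 in wild type 3 and 4 and 0.32 to 1.01 in Ncoa5+/-, so the groups overlapped, and without wild type 4 the call stood at 0.000748. Of 10 cholangiocyte markers 3 rose adjusted over the list alone, with Spp1 at log2 1.05 (adjusted p = 0.0529; list 0.000447, and adjusted p = 0.383 with an estimated correlation). Of 18 stellate cell and matrix genes 1 rose adjusted over the list alone, with Col1a1 at log2 1.07 (adjusted p = 0.138; list 0.0155, and adjusted p = 0.649 with an estimated correlation). The matrix call was lost without wild type 3 (adjusted p = 0.101), wild type 4 (0.11), Ncoa5+/- 2 (0.082) or Ncoa5+/- 4 (0.328). Cd8a kept its call in all 8 fits without 1 mouse and had an adjusted p of 0.0556 in a fit of the 2 groups alone (2.98e-07 to 0.0556 over all settings). Relb lost its call in 6 of 8 fits without 1 mouse (up to 0.102), Icam1 in 7 (up to 0.0957), Cxcl9 without wild type 3 (0.0642) or wild type 4 (0.0526) and Nkg7 without Ncoa5+/- 2 (0.0534) or Ncoa5+/- 4 (0.0506).

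Lists of growth and metabolism were also called in mice labelled Ncoa5+/-. The cell cycle list of 27 genes was called up (adjusted p = 1.45e-06, and adjusted p = 0.383 with an estimated correlation), with 1 member up adjusted over the list alone, Ccnd1 of cyclin D1 (log2 1.59, adjusted p = 0.0566). Immediate early genes (0.00212), NRF2 targets (0.0034) and the HCN family (0.00818) were called up as well, with Dusp6 at log2 0.74, Srxn1 at 0.47 and Gstm3 at 1.06, none of which passed. Their calls were lost as well (adjusted p = 0.306, 0.436 and 0.306 with an estimated correlation), and that of NRF2 targets was lost without Ncoa5+/- 1 (0.0921). Ephx1, a xenobiotic epoxide hydrolase gene (log2 1.02, adjusted p = 0.0144), and Sesn2 (log2 1.18, 0.0396) rose within lists that were not called. Called down were the 15 mitochondrially encoded genes (adjusted p = 7.31e-06), cholesterol synthesis (0.000912) and bile acid synthesis and transport (0.00831), and none of these calls held (adjusted p = 0.436, 0.643 and 0.383 with an estimated correlation). Examples are CYTB at log2 -0.76 (adjusted p = 0.246), Msmo1 at -0.52 (0.376) and Cyp7b1, an oxysterol hydroxylase gene, at -1.13 (0.138). In the bile acid list 1 of 22 fell adjusted over the list alone. The cholesterol call was lost without wild type 1 (0.0577) or Ncoa5+/- 4 (0.328), and the bile acid call without wild type 4 (0.11). Without the 4 livers low in Zhx2 the direction of cholesterol synthesis reversed (0.191). Fetal liver and tumour markers were called up (adjusted p = 0.0163, and adjusted p = 0.504 with an estimated correlation), with 2 of 13 up adjusted over the list alone, Ly6d at log2 3.83 (adjusted p = 0.104, and log2 4.57 with adjusted p = 0.0415 without Ncoa5+/- 3) and Afp, the alpha-fetoprotein gene, at 1.79 (0.179, and log2 1.17 without Ncoa5+/- 4). Afp stood at 567 and 1501 normalized counts in Ncoa5+/- 1 and 4, which are livers low in Zhx2, and at 190 and 172 in Ncoa5+/- 2 and 3. The other livers low in Zhx2, wild type 1 and 2, had the lowest Afp of the 16, at 100 and 91.5, against 168 and 124 in wild type 3 and 4, so low Zhx2 did not go with high Afp there. The fetal call was lost without wild type 3 (0.0551), wild type 4 (0.174), Ncoa5+/- 1 (0.0921) or Ncoa5+/- 4 (0.141).

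Tip30+/- livers differed from wild type in 2 genes by limma, and both have been described: Hcn3 rose and Htatip2 fell. The count at an unadjusted p under 0.05 was 1121, where chance gives 763, and the groups did not overlap for 678 genes, or 4.44% against 2.86% by chance. The next smallest p values belonged to the ubiquitin ligase gene Trim6 (log2 -2.08 ± 0.36, adjusted p = 0.098), the purinergic receptor gene P2ry2 (0.95 ± 0.18, 0.194), the G protein gene Gna14 (1.18 ± 0.23, 0.194) and Wnt5a, a Wnt ligand gene (-0.83 ± 0.16, 0.194). By DESeq2 43 genes passed and without the 4 livers low in Zhx2 6 did. Wild type 1 and 2 are among these 4 and no Tip30+/- liver is, so the contrast also carries that difference between livers. The limma count was 1 without wild type 2, Tip30+/- 1 or Tip30+/- 3, 4 without wild type 3 or Tip30+/- 2, and 8 without Tip30+/- 4.

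Of the 37 lists, 13 were called in Tip30+/- livers, 7 up and 6 down, none of them with an estimated correlation, and Hcn3 was the only member that passed over all genes. Called up were the HCN family (adjusted p = 0.00153), fatty acid and triglyceride synthesis (0.00216), fatty acid oxidation and PPAR-alpha targets (0.00216), pericentral genes (0.00855), clock genes (0.00855), cholangiocyte markers (0.022) and nuclear-encoded oxidative phosphorylation (0.0347). The values were adjusted p = 0.246, 0.6, 0.657, 0.6, 0.6, 0.657 and 0.71 with an estimated correlation. In lipid synthesis 2 of 27 rose adjusted over the list alone, Pklr and the triglyceride synthesis gene Dgat2 (log2 0.46, adjusted p = 0.422), and Hcn3 was the only such member of the other lists called up. Examples of the others are Acot4 at 0.67, the clock gene Per1 at 1.09, Tbx3 at 0.48, Cldn7 at 1.57 and Ndufb8 at 0.19. Called down were type I interferon genes (8.93e-05), heat shock genes (0.00153), unfolded protein response (0.00827), ribosomal proteins (0.00827), cell cycle (0.00855) and neutrophil markers (0.00855). The values were adjusted p = 0.657, 0.6, 0.6, 0.71, 0.657 and 0.6 with an estimated correlation. Adjusted over the list alone, 1 neutrophil marker fell, S100a9 (log2 -1.20, adjusted p = 0.552), and in the unfolded protein list 2 fell and 1 rose, with Manf at -0.69 and Herpud1 at 0.79 (0.454 each). Rsad2 at log2 -0.87, Hspb1 at -1.37, Rplp0 at -0.29 and Top2a at -0.91 are examples from the other lists called down. Calls lost without 1 mouse were cell cycle (wild type 1, 0.643), pericentral (wild type 1, 0.104), clock (wild type 4, 0.0514), neutrophils (Tip30+/- 4, 0.112) and unfolded protein response (Tip30+/- 3, 0.144). Those of cholangiocytes (up to 0.404), oxidative phosphorylation (up to 0.404) and ribosomal proteins (up to 0.116) were each lost in 3 of 8 fits. Without the 4 livers low in Zhx2 the direction of interferon genes (adjusted p = 0.692), cell cycle (0.692) and oxidative phosphorylation (0.803) reversed.

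The double heterozygotes were compared with wild type to ask what the loss of both alleles changes together. Wild type 1 and 2 were low in Zhx2 and no double heterozygote was, so this contrast also carries that difference between livers. p53 targets were again the group that moved most: 13 of 21 rose and none fell, and 14 rose and 1 fell adjusted over the list alone. Phlda3 rose 32.3-fold (log2 5.01 ± 0.47, adjusted p = 8.46e-05), Eda2r 22.7-fold (4.50 ± 0.46, 7.82e-05), Cdkn1a 21.7-fold (4.44 ± 0.43, 0.000118) and the pro-apoptotic gene Bax 2.58-fold (1.37 ± 0.16, 0.000189). The list was called up (adjusted p = 6.51e-17, and adjusted p = 0.136 with an estimated correlation, the highest over all settings). Gdf15 rose 7.34-fold (adjusted p = 0.00332) and Tnfrsf10b 8.68-fold (0.000951). Outside that list Gria3 rose 28.9-fold (log2 4.85 ± 0.41, adjusted p = 2.27e-05), Lif 17.7-fold (0.0055), Ddit4l 16.2-fold (8.06e-05), Fam212b by log2 4.00 ± 0.49 (0.000254), Sec14l5 8.54-fold (0.0188) and Mir692-1 16.9-fold (0.00531). The sulfotransferase gene Sult2a7 rose 67.6-fold (log2 6.08 ± 1.26, adjusted p = 0.0271), from 26.9 ± 24.8 to 1476 ± 885 normalized counts (SD), and the change was log2 5.46 without wild type 2 (adjusted p = 0.0676). Sult2a7 has close paralogs and Mir692-1 is a short microRNA gene, so the assignment of reads to both is uncertain. In mice labelled Ncoa5+/- Sult2a7 stood at 1054 and 882 in mice 2 and 3 and at 46.2 and 12.7 in mice 1 and 4, the mice low in Zhx2.

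Among genes that fell in double heterozygotes were hydroxylase genes of bile acid synthesis. Cyp8b1, the sterol hydroxylase that sets cholic acid output, fell (log2 -2.02 ± 0.43, adjusted p = 0.0292), and so did Cyp7b1 (-1.75 ± 0.30, 0.0069) and Cyp39a1, another oxysterol hydroxylase gene (-1.62 ± 0.39, 0.04). The PPAR-alpha target Cyp4a14 (log2 -2.18 ± 0.36, 0.00645), Selenbp2 (-2.96 ± 0.57, 0.0191), the Wnt ligand gene Wnt5a (-1.30 ± 0.16, 0.000313) and Plppr1 (-2.30 ± 0.56, 0.0396) fell too. The remaining named genes, Fndc5, Abtb2, Pm20d2, Zfp518a and Atp6v0e2, had log2 changes of -1.25 to -1.08. Cyp4a14 and Selenbp2 have close paralogs, so the assignment of their reads is uncertain. In all 407 genes changed, 213 up and 194 down, and by more than 2-fold 144 and 23. The share that rose was 52.3%, and with upper-quartile scaling 69.6% of 388. Groups did not overlap for 1633 genes, or 10.7% against 2.86% by chance. The count was 88 without Ncoa5+/-Tip30+/- 2, 108 without wild type 1, 167 without wild type 4, 196 without Ncoa5+/-Tip30+/- 3, 216 without wild type 2, 651 without Ncoa5+/-Tip30+/- 4 and 846 without wild type 3. It was 1044 by DESeq2, 697 with the mouse tag range as a covariate, 107 in a fit of these 2 groups alone, 253 with Zhx2 as a covariate and 121 without the 4 livers low in Zhx2, of which 86.0% rose. Calls lost in at least 4 of 8 fits without 1 mouse were Plppr1 (up to 0.148), Cyp39a1 (0.149), Pm20d2 (0.159), Cyp8b1 (0.0875), Fndc5 (0.0935), Sult2a7 (0.0954) and Sec14l5 (0.087). Selenbp2 lost it without wild type 1 (0.0615), wild type 2 (0.0528) or Ncoa5+/-Tip30+/- 2 (0.0728) and Atp6v0e2 without wild type 1 (0.0707) or wild type 2 (0.0557). Genes called in all 8 such fits but lost without the livers low in Zhx2 or with the 2 groups alone were Relb (up to 0.0554), Cyp7b1 (1.34e-07 to 0.0805 over all settings), Mir692-1 (2.98e-09 to 0.0972), Zfp518a (3.84e-05 to 0.113) and Gdf15 (1.64e-09 to 0.0582).

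Of the 37 lists, 16 were called in double heterozygotes, 11 up and 5 down, and none with an estimated correlation. NF-kB and cytokine genes were called up (adjusted p = 0.00108, and adjusted p = 0.34 with an estimated correlation): 3 of 17 rose, and 4 adjusted over the list alone, with Relb at log2 1.05 ± 0.18 (adjusted p = 0.0055), Icam1 at 0.58 ± 0.13 (0.0264) and Cxcl9 at 1.09 ± 0.28 (0.0473). Lymphocyte markers were called up (0.000179, and adjusted p = 0.694 with an estimated correlation): 1 of 18 rose, Cd8a (log2 2.97 ± 0.53, adjusted p = 0.00651), and 3 adjusted over the list alone. Of 10 cholangiocyte markers Spp1 rose (log2 1.20 ± 0.23, adjusted p = 0.0137), and 4 adjusted over the list alone (list 0.0117, and adjusted p = 0.694 with an estimated correlation). Of 8 erythroid genes Alas2, which starts heme synthesis, rose (log2 0.96 ± 0.23, 0.0342; list 0.0326, and adjusted p = 0.774 with an estimated correlation). Of 22 bile acid genes Cyp7b1 and Cyp8b1 fell (list down, 0.0203, and adjusted p = 0.694 with an estimated correlation). Among 25 cholesterol synthesis genes Srebf2, the regulator of the pathway, fell (log2 -0.55 ± 0.11, 0.0191), and 4 fell adjusted over the list alone (list down, 0.0134, and adjusted p = 0.833 with an estimated correlation). Of 15 heat shock genes 5 fell adjusted over the list alone, with Hsph1 at log2 -0.92 (adjusted p = 0.0581; list 0.00359, and adjusted p = 0.694 with an estimated correlation). The HCN family was called up (0.00303, and adjusted p = 0.181 with an estimated correlation), with Hcn3 up over all genes and both tested members up adjusted over the list alone.

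The other lists called in double heterozygotes had no member that passed over all genes. They were, up, interferon (adjusted p = 0.00804), lipid synthesis (0.0203), cell cycle (0.0218), macrophages and Kupffer cells (0.0326) and stellate cells and matrix (0.0326), and, down, mitochondrially encoded genes (0.0251) and the growth hormone axis (0.0326). The values were adjusted p = 0.833, 0.774, 0.833, 0.835, 0.833, 0.833 and 0.694 with an estimated correlation. Examples are Oas2 at log2 1.10 (adjusted p = 0.064), the lipase gene Pnpla3 at 3.23 (0.109), Ccnb2 at 1.25 (0.0806), C1qa at 0.56 (0.191), Dcn at 0.41 (0.103), CYTB at -0.86 (0.0691) and Bcl6 at -0.68 (0.125). Adjusted over the list alone, 1 of the 15 mitochondrially encoded genes fell and no member of the other 6 lists passed. The calls of bile acids (0.0569 and 0.167) and lipid synthesis (0.164 and 0.0891) were lost without wild type 3 or wild type 4, and that of cholesterol without wild type 1 (0.0785) or Ncoa5+/-Tip30+/- 4 (0.184). The number of called lists was 7 without wild type 3 or wild type 4 and 10 without Ncoa5+/-Tip30+/- 2. Interferon (up to 0.2), cell cycle (0.235) and mitochondrially encoded genes (0.286) lost theirs in 3 of 8 fits, erythroid genes in 4 (0.255), and macrophages (0.658), matrix (0.196) and growth hormone axis (0.169) in 5. Members that lost their call were Icam1 (in 3 of 8 fits, up to 0.0903), Cxcl9 (6, 0.168) and Alas2 (5, 0.115), and Spp1 and Srebf2 lost it without wild type 1 (0.0539 and 0.0682) or Ncoa5+/-Tip30+/- 2 (0.0613 and 0.0808).

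What the Tip30 deletion adds to the Ncoa5 deletion was asked by comparing double heterozygotes with mice labelled Ncoa5+/-. By limma 3 genes changed: Htatip2 fell by 1.33 ± 0.13 (adjusted p = 0.000139), and the processed pseudogenes Gm11478 and Gm6394 rose 2.55-fold (log2 1.35 ± 0.21) and 20.9-fold (4.39 ± 0.65), each with an adjusted p of 0.0306. Gm6394 stood at 120 to 198 normalized counts in the double heterozygotes, at 153 to 177 in 3 Tip30+/- mice and at 10.2 in the last one, and the assignment of reads to pseudogenes is uncertain. Without 1 mouse, Gm11478 lost its call in 7 of 8 fits and Gm6394 in all 8, at adjusted p up to 0.212. Gm6394 had an adjusted p of 4.03e-12 to 0.942 over all settings, highest without the livers low in Zhx2. The next smallest p values belonged to Ftl1-ps2 (log2 3.59), Gm12164 (2.78) and Hcn3 (1.21), each with an adjusted p of 0.174. The count at an unadjusted p under 0.05 was 1363 against 763 by chance, and groups did not overlap for 732 genes, or 4.80% against 2.86%. The limma count was 1 in 7 of the 8 fits without 1 mouse, all but the fit without Ncoa5+/- 4, which gave 2. It was 32 by DESeq2, 7 without robust variance moderation, 9 in a fit of the 2 groups alone, and 1 with sample weights or without the livers low in Zhx2. Ncoa5+/- 1 and 4 were low in Zhx2 and no double heterozygote was, so that difference between livers enters this contrast too.

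Of the 37 lists, 6 were called between double heterozygotes and mice labelled Ncoa5+/-, with no member passing over all genes and each with an adjusted p of 0.974 with an estimated correlation. Interferon genes (adjusted p = 0.00147), acute phase genes (0.00469), heat shock genes (0.00469) and the unfolded protein response (0.019) were called down. Examples are Irf9 at log2 -0.36, Itih3 at -0.55, Hsph1 at -0.61 and Hspa5, the chaperone BiP, at -0.57. Lipid synthesis (0.00852) and the HCN family (0.019) were called up, and adjusted over the list alone 1 member of each rose, the carbohydrate-response factor gene Mlxipl (log2 0.93, adjusted p = 0.475) and Hcn3. Without 1 mouse the acute phase call was lost without Ncoa5+/- 1 (0.112), lipid synthesis without Ncoa5+/- 4 (0.327) and heat shock without Ncoa5+/-Tip30+/- 4 (0.0538). The HCN call was lost without Ncoa5+/- 4, Ncoa5+/-Tip30+/- 3 or Ncoa5+/-Tip30+/- 4 (up to 0.081), and the unfolded protein call without Ncoa5+/- 1, Ncoa5+/-Tip30+/- 2 or Ncoa5+/-Tip30+/- 4 (up to 0.0941).

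What the Ncoa5 deletion adds to the Tip30 deletion was asked by comparing double heterozygotes with Tip30+/- mice. p53 targets rose here as well, 14 of 21 over all genes with none that fell, and 15 up and 1 down adjusted over the list alone. Phlda3 rose 45.4-fold (log2 5.51 ± 0.47, adjusted p = 3.21e-05), Cdkn1a 33.6-fold (5.07 ± 0.43, 3.21e-05), Eda2r 28.0-fold (4.81 ± 0.46, 3.21e-05) and Bax 2.86-fold (1.52 ± 0.16, 4.32e-05). The list was called up (adjusted p = 3.08e-18, and adjusted p = 0.106 with an estimated correlation, the highest over all settings). Lif had 1 read in 1 of 4 Tip30+/- livers and 70.3 normalized counts on average in double heterozygotes (adjusted p = 0.000731), so no fold is given. Further genes that rose were Gria3 (34.4-fold, adjusted p = 5.85e-06), Ddit4l (19.9-fold, 3.21e-05), Fam212b (18.1-fold, 0.00015), Tnfrsf10b (18.0-fold, 4.32e-05), Sec14l5 (17.7-fold, 0.00246), Ddias (9.55-fold, 0.000603), Gdf15 (7.24-fold, 0.00368) and Sult2a7 (33.6-fold, 0.0499). Sec14l5 had 2.19 normalized counts in Tip30+/- livers, so its fold is uncertain. Those that fell included Steap2 (fell by 1.65 ± 0.36, 0.0246), the Wnt receptor gene Fzd8 (fell by 1.18 ± 0.25, 0.0243), the cation transporter gene Slc22a3 (fell by 1.17 ± 0.25, 0.0239), the glutamate transporter gene Slc1a2 (fell by 1.04 ± 0.23, 0.0292) and Hnf4aos (fell by 0.92 ± 0.23, 0.0389). The other named genes that fell, Klhl13, Syde2, Ttc7b, Chpt1, B4galt5, Cyp2a5 and Tarsl2, had log2 changes of -1.09 to -0.81.

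In all 469 genes changed between double heterozygotes and Tip30+/- mice, 245 up and 224 down, and by more than 2-fold 147 and 13. The share that rose was 52.2%, and it was 74.6% of 421 with upper-quartile scaling, 63.4% of 402 with TMM scaling, 66.3% of 407 by edgeR and 62.8% of 400 by limma-voom. Groups did not overlap for 2465 genes, or 16.2% against 2.86% by chance. The count was 107 without Ncoa5+/-Tip30+/- 2, 131 without Tip30+/- 2, 162 without Tip30+/- 4, 164 without Ncoa5+/-Tip30+/- 3, 178 without Tip30+/- 3, 184 without Tip30+/- 1, 307 without Ncoa5+/-Tip30+/- 1 and 764 without Ncoa5+/-Tip30+/- 4. It was 1118 by DESeq2, 749 with sample weights and 1344 with the mouse tag range as a covariate. The p53 targets named, Gria3, Ddit4l, Fam212b, Sec14l5, Lif and Ddias kept their calls in all 8 fits without 1 mouse. Sult2a7, Hnf4aos, Cyp2a5 and Tarsl2 lost theirs in 7 (up to 0.155, 0.134, 0.135 and 0.165), Slc1a2 and Chpt1 in 6 (0.0976 and 0.0927), Steap2 and Fzd8 in 5 (0.0961 and 0.0996), Slc22a3, Syde2, Ttc7b and B4galt5 in 3 (up to 0.0992) and Klhl13 without Ncoa5+/-Tip30+/- 2 (0.0591).

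Lists of immune and cell cycle genes were called up in double heterozygotes against Tip30+/- mice. Interferon genes were called up (adjusted p = 6.59e-09, and adjusted p = 0.572 with an estimated correlation): Bst2 rose (log2 0.64 ± 0.17, adjusted p = 0.045), and 9 of 28 adjusted over the list alone. Cell cycle genes were called up (6.22e-05, and adjusted p = 0.572 with an estimated correlation): Ccnd1 rose (log2 1.53 ± 0.34, adjusted p = 0.0304), and 3 of 27 adjusted over the list alone. Ccnd1 stood at 7208 normalized counts in Ncoa5+/-Tip30+/- 3 and at 2189 to 2938 in the other 3. Lymphocyte markers were called up (0.000242, and adjusted p = 0.572 with an estimated correlation), and 3 of 18 rose over all genes and over the list alone: Cd8a (8.57-fold, 0.00541), Lck (1.15 ± 0.28, 0.0341) and Nkg7 (1.18 ± 0.29, 0.0406). NF-kB genes were called up (0.00157, and adjusted p = 0.463 with an estimated correlation), and 3 of 17 rose, and 4 adjusted over the list alone: Icam1 (log2 0.56 ± 0.13, 0.0316), Ccl5 (1.75 ± 0.46, 0.0476) and Relb (0.70 ± 0.18, 0.0476). Neutrophil markers (0.0182, with S100a9 at log2 1.11) and ribosomal proteins (0.049, with Rps19 at 0.44) were called up without a member that passed over all genes (adjusted p = 0.572 and 0.642 with an estimated correlation), and 2 neutrophil markers rose adjusted over the list alone. Bst2, Ccl5, Relb and Nkg7 lost their calls in 7 of 8 fits without 1 mouse (up to 0.177), Lck in 6 (0.142), Icam1 in 5 (0.0923) and Ccnd1 in 3 (0.0812).

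Lists of hepatocyte functions were called down in the same comparison. Of 17 genes of the growth hormone axis the receptor gene Ghr fell (log2 -0.58 ± 0.15, adjusted p = 0.0433), and 3 adjusted over the list alone (list 0.00157, and adjusted p = 0.463 with an estimated correlation). Of 22 bile acid genes the uptake transporter gene Slc10a1 fell (-0.63 ± 0.13, 0.0191), and 3 adjusted over the list alone (list 0.00225, and adjusted p = 0.516 with an estimated correlation). Of 20 gluconeogenesis genes Sds fell (-0.70 ± 0.15, 0.0226), and 2 adjusted over the list alone (list 0.049, and adjusted p = 0.602 with an estimated correlation), and of 25 cholesterol genes 3 fell adjusted over the list alone, with Stard4 at -0.53 (0.0788; list 0.0498, and adjusted p = 0.642 with an estimated correlation). Of 30 xenobiotic genes Cyp2a5 fell (-0.82 ± 0.20, 0.0393) and Ephx1 rose (0.90 ± 0.19, 0.0194), and 3 fell and 1 rose adjusted over the list alone (list 0.0305, and adjusted p = 0.608 with an estimated correlation). No member passed over all genes among mitochondrially encoded genes (0.00225), fatty acid oxidation (0.0112) and female-biased liver genes (0.034), whose calls were lost as well (adjusted p = 0.608, 0.608 and 0.572 with an estimated correlation). Adjusted over the list alone 5 of 15, 7 of 28 and none of 28 fell, with CYTB at log2 -0.93 (adjusted p = 0.0513), Hadh at -0.43 (0.0518) and Sult2a2 at -0.63 (0.0602). Lost without 1 mouse were the calls of cholesterol (up to 0.353), gluconeogenesis (0.107), ribosomal proteins (0.434), female-biased genes (without Tip30+/- 2 or Ncoa5+/-Tip30+/- 3, up to 0.0969), xenobiotic genes (without Tip30+/- 3 or Ncoa5+/-Tip30+/- 2, up to 0.07) and fatty acid oxidation (without Ncoa5+/-Tip30+/- 3, 0.106). Among members, Ghr lost its call in 7 of 8 such fits (up to 0.151), and Slc10a1, Sds and Ephx1 in 4 (0.0848, 0.0848 and 0.0857).

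Whether both deletions together depart from the sum of each was tested by the interaction term on the log2 scale. No gene passed by limma (smallest adjusted p = 0.95, 650 genes at an unadjusted p under 0.05, where chance gives 763), none by edgeR or limma-voom and 1 by DESeq2. On simulated data, with changed genes of a mean of at least 50, the same test recovered 48.4% given a 2-fold and 89.1% given a 4-fold departure. Smaller departures would mostly be missed. The genes with the smallest p were Gm44891 (log2 2.17), Cyp21a2-ps (1.65), Gm3235 (3.49), Riox1 (-0.77), Gm6652 (-0.98) and 2310016G11Rik (2.33). The lists of fatty acid oxidation (adjusted p = 3.12e-05), pericentral genes (0.0389) and macrophages (0.0414) were called down and ribosomal proteins (0.00221) up, with no member passing over all genes or over the list alone. Neither the estimated correlation nor fry called any of the 4 (adjusted p by fry = 0.765, 0.765, 0.781 and 0.765). Examples are Hadh at log2 -0.40, Glul, the pericentral glutamine synthetase gene, at -0.49, Lyz2 at -0.62 and Rps20 at 0.32. Without 1 of the 16 mice the pericentral call was lost in 8 fits (up to 0.265), that of macrophages in 6 (0.523) and that of ribosomal proteins without Ncoa5+/- 4, Tip30+/- 1 or Ncoa5+/-Tip30+/- 2 (up to 0.154). The number of called lists was 7 without wild type 3, Ncoa5+/- 2 or Tip30+/- 2, 8 without wild type 4, 2 without Ncoa5+/- 3, Ncoa5+/- 4, Ncoa5+/-Tip30+/- 2 or Ncoa5+/-Tip30+/- 4 and 1 without Tip30+/- 1.

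The contrasts with wild type share the same 4 control mice, which alone makes them alike. Mice labelled Ncoa5+/- and double heterozygotes shared 67 genes called in the same direction, 65 up and 2 down, and none in opposite directions. Independent lists would share 1.13 up and 0.0508 down, and simulated unchanged groups that share 1 control group shared 0.02 on average and 2 at most. Groups without any change give few calls, so this simulated number cannot show how many of the 67 come from the shared controls. With the controls split into separate pairs for each contrast, 20 to 46 genes were shared. Over genes, which are not independent replicates, the log2 changes had r = 0.65 and a covariance of 0.124, against a mean r of 0.478 (-0.14 to 0.83) and a mean covariance of 0.0475 (0.116 at most) in the simulations, so this r lies within their range. The splits gave r of -0.12 to 0.50 and covariances of -0.0437 to 0.105. Tip30+/- and double heterozygotes shared Hcn3 and Htatip2 (r = 0.378, simulated mean 0.45 and range -0.66 to 0.80, covariance 0.0688, split covariance -0.0824 to 0.0608, 1 to 3 shared genes in the splits). Independent lists would share 0.014 up and 0.0127 down, and the simulated covariance was 0.0462 on average and 0.143 at most. Ncoa5+/- and Tip30+/- shared Hcn3 alone (r = 0.0813, simulated mean 0.485 and range -0.63 to 0.84, covariance 0.0122, split covariance -0.192 to -0.0109, 0 shared genes in the splits). Independent lists would share 0.00531 up and 0.000262 down, and the simulated covariance was 0.0496 on average and 0.146 at most.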

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

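All tests in this part were chosen only after the results they concern were seen. Single libraries far from the other 3 of their group were found in 24 of 676 group tests, where chance gives about 1 in 20, or 33.8, so the single values carry little weight.

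Hcn3 was higher than wild type in all 12 heterozygous livers, and its annotated exons share 711 bases with Pklr. Reads of Pklr argue against being the whole source, since log2(Hcn3/Pklr) lay above wild type by 1.07 ± 0.18, 0.86 ± 0.18 and 1.80 ± 0.18 in Ncoa5+/-, Tip30+/- and double heterozygotes, the smallest being 0.861. With Pklr as a covariate the Tip30+/- change went from log2 1.74 ± 0.23 (adjusted p = 0.0099) to 1 ± 0.26 (0.566; 1.24e-09 to 0.566 over all settings), a call that ended because the change shrank and its SE grew, while Ncoa5+/- stood at 1.08 ± 0.17 (0.00483) and double heterozygotes at 1.88 ± 0.21 (0.00058). The mouse tag range is argued against as the whole source by differences of at least 2.14 ± 0.39 between double heterozygotes and wild type within each range (2 mice against 2). A part of the Tip30+/- rise may come from Pklr reads, and an effect of the 2 genotypes on Hcn3 stays open as a hypothesis.

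p53 targets were higher in all 8 livers labelled with the Ncoa5 deletion than in the other 8, while Ncoa5 messenger RNA itself was at 89.5% of wild type in mice labelled Ncoa5+/-. The 21 lymphocyte markers, counting only members that were higher, rose by 233 normalized counts, 1.49% of the 15589 of the p53 targets. A first version that let members cancel gave 25.2 counts and was replaced by this one, which favours the explanation more. How many reads of p53 targets lymphocytes give per marker read is not known, so this share cannot decide whether they contribute. The mouse tag range is argued against as the whole source by differences in list mean within each range (2 mice against 2). Against wild type they were at least 1.79 ± 0.35 for Ncoa5+/- and at least 1.64 ± 0.35 for double heterozygotes. Exchanged labels cannot be told apart from a genotype effect, since Ncoa5 counts overlapped (339 to 424 in the 8 and 380 to 480 in the others, with 3 of the 8 below all others) and so do not check the labels. Strain variants, husbandry, or an exposure shared by these 8 mice were not tested, so an effect of the Ncoa5 deletion may explain the pattern and remains a hypothesis.

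Zhx2, a repressor of fetal liver genes, stood at 19.4 and 26.3 normalized counts in wild type 1 and 2 and at 13.5 and 8.77 in Ncoa5+/- 1 and 4, and at 167 to 438 in the other 12 livers. In the same 4 livers H19 stood at 615 to 2885, Lpl at 543 to 1731, Gpc3 at 92.5 to 125, Elovl3 at 0 to 1.13 and Mup12 at 4.87 to 14.6. Afp did not follow them, with 100 and 91.5 in wild type 1 and 2, 567 and 1501 in Ncoa5+/- 1 and 4 and 124 to 225 in the other 12. The mouse tag range is argued against as the whole source, since 3 of the 4 had tags under 4300 and 6 other livers there were not low. Whether the Tip30 genotype matters cannot be told apart from chance, since 0 of 8 livers with the Tip30 deletion and 4 of 8 without it were low (Fisher exact p = 0.0769). The mouse strain is not given in the sources used here, and a Zhx2 variant segregating in the colony was not tested but may be a candidate explanation.

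The wild-type libraries that stood apart, each with the range of the other 3, were wild type 2 for Lif (7.36 against 0.86 to 1.02), Relb (67.3 against 43.1 to 46.4) and Acot4 (2329 against 3115 to 3264), and wild type 3 for Dusp6 (1490 against 894 to 954). Ncoa5+/- 1 stood apart for Phlda3 (4371 against 1744 to 1820), Ddit4l (385 against 120 to 143), Gna14 (27.0 against 41.8 to 42.7) and Slc1a2 (1444 against 1756 to 1766). Ncoa5+/- 2 stood apart for Mlxipl (8509 against 4084 to 4555), Ncoa5+/- 3 for Chpt1 (1774 against 1148 to 1222), Tarsl2 (334 against 222 to 241) and Spp1 (841 against 1191 to 1258), and Ncoa5+/- 4 for Ccnb2 (50.7 against 21.9 to 26.5). Tip30+/- 4 stood apart for Lif (1.02 against 0), Gm6394 (10.2 against 153 to 177) and Gm3235 (1.02 against 4.86 to 5.12), and Tip30+/- 3 for Irf7 (568 against 703 to 717). Ncoa5+/-Tip30+/- 3 stood apart for Ccnd1 (7208 against 2189 to 2938) and Rgn (36980 against 41170 to 41780), Ncoa5+/-Tip30+/- 1 for Fzd8 (1071 against 705 to 761) and Ncoa5+/-Tip30+/- 2 for Col1a1 (463 against 355 to 368). List means on the log2 scale stood apart in Ncoa5+/-Tip30+/- 1 for immediate early genes (-0.25 against 0.51 to 0.61), in Ncoa5+/-Tip30+/- 3 for fatty acid oxidation (-0.24 against 0.09 to 0.16) and in Ncoa5+/-Tip30+/- 2 for xenobiotic metabolism (-0.41 against -0.08 to -0.07).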

How the results depend on the processing

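The settings without the 4 livers low in Zhx2, with a Zhx2 covariate and with a Pklr covariate were chosen after seeing the data, and where no reason is given the cause was not tested. Of 3048 values of named genes under settings other than leaving out 1 mouse, 2847 kept their direction and side of the threshold, 132 lost a call, 69 gained one and 0 reversed, and of 1784 values without 1 mouse 1520, 245, 19 and 0. Of 483 such values for gene lists 309 kept theirs, 170 lost a call and 4 reversed, and of 584 values without 1 mouse 482 kept theirs and 102 lost a call. Depth limits what can be said of genes with a mean under 10 normalized counts, which were not tested, and of folds from groups near 0, such as that of Lif.

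DESeq2 called 257 genes for Ncoa5+/- against wild type, 43 for Tip30+/- and 1044 for double heterozygotes, 32 and 1118 for double heterozygotes against Ncoa5+/- and Tip30+/-, and 1 for the interaction. With only the 2 groups compared the counts were 56 for Ncoa5+/- against wild type, 107 for double heterozygotes against wild type and 9 against Ncoa5+/-. With the mouse tag covariate, double heterozygotes differed from wild type in 697 genes and from Tip30+/- in 1344. Without the 4 livers low in Zhx2, and so with fewer mice, the counts were 29 for Ncoa5+/-, 6 for Tip30+/- and 121 for double heterozygotes against wild type, and 1 for double heterozygotes against Ncoa5+/-. With the Zhx2 covariate double heterozygotes differed from wild type in 253 genes. Double heterozygotes differed from Ncoa5+/- in 7 genes when variance moderation was not robust and in 1 with sample weights, which gave 749 against Tip30+/-. Without 1 mouse the counts ran from 45 to 88 for Ncoa5+/-, 1 to 8 for Tip30+/- and 88 to 846 for double heterozygotes against wild type, and 1 to 2 and 107 to 764 against Ncoa5+/- and Tip30+/-.

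The log2 change of Hcn3 in Ncoa5+/- was 1.16 (adjusted p = 0.17) with only the 2 groups compared and 0.98 to 1.37 without 1 mouse. In Tip30+/- it was 1.59 (0.0569) with the Zhx2 covariate, 1 (0.566) with the Pklr covariate and 1.62 to 1.87 without 1 mouse. Over all settings its adjusted p ran from 0.000102 to 0.17 and from 1.24e-09 to 0.566.

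An estimated correlation left 1 list called for Ncoa5+/- against wild type and 0 in each of the other 5 comparisons, since it allows for members that vary together, with p53 targets at 0.136 for double heterozygotes against wild type and 0.106 against Tip30+/-. Fry called 3, 1 and 3 lists for Ncoa5+/-, Tip30+/- and double heterozygotes against wild type, 0 and 4 against Ncoa5+/- and Tip30+/-, and 0 for the interaction. The Zhx2 covariate gave 8 lists for Tip30+/- against wild type and 3 for double heterozygotes against Ncoa5+/-, the fit without the 4 livers 1 for the latter, and upper-quartile scaling 8 for the interaction. Without 1 mouse 7 to 17 lists were called for double heterozygotes against wild type and 1 to 8 for the interaction. Without the 4 livers low in Zhx2 the direction reversed for cholesterol synthesis in Ncoa5+/- (adjusted p = 0.191), and for cell cycle (0.692), interferon (0.692) and nuclear-encoded oxidative phosphorylation (0.803) in Tip30+/-. With wild type split into pairs, Ncoa5+/- and double heterozygotes shared 20 genes at the fewest, Tip30+/- and double heterozygotes 1, and Ncoa5+/- and Tip30+/- 0 at the fewest and 0 at the most.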

Other observations

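The tests of neighbouring genes and the splits of libraries in this part were chosen only after the results were seen, while the gene lists were planned. Genes near Htatip2 were counted among the 100 genes of smallest p to ask whether variants linked to the Tip30 deletion may add to the differences. Within 20 Mb lay 15 of them for Tip30+/- against wild type (mean 1.84 and highest 16 over 15228 shifted windows, permutation p = 0.00315) and 10 for double heterozygotes against Ncoa5+/- (highest 10, permutation p = 0.00315). The shifts include small ones that keep most of the same genes in the window. The highest values therefore do not show that another place in the genome reached them. Within 20 Mb of Ncoa5 lay 2 for Ncoa5+/- against wild type (permutation p = 0.656) and 1 for double heterozygotes against Tip30+/- (permutation p = 0.868), so no excess of genes near Ncoa5 was found, while linked variants that act on genes elsewhere were not tested. Hnf4aos, which fell in both comparisons, lies within that window (chromosome 2, 163493807 to 163541720). Whether a variant linked to the Ncoa5 deletion acts on Hnf4aos was not tested. Variants linked to the Htatip2 deletion are thus a hypothesis for part of the Tip30 differences, and no variants were examined here.

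The libraries of each pair of groups were divided in 35 ways, the real one included. For double heterozygotes against wild type no other split called as many genes (407 genes, 1 in the highest other split, 1 of 35 as large). The same held against Tip30+/- (469, 1 in the highest other, 1 of 35). This is the smallest share that 35 splits allow, so chance is not excluded as the source of these numbers. The other splits also mix both genotypes within a group, which widens the spread and lowers their counts. Chance cannot be excluded for the number in Tip30+/- against wild type (2 genes, 2 in the highest other, 2 of 35 as large), although 1 of the 2 is the deleted gene Htatip2, called in all 8 fits without 1 mouse (adjusted p up to 0.000663). For the number in Ncoa5+/- against wild type chance cannot be excluded either: 2 of 35 splits called as many, with 85 in the real one and 221 in the split that puts wild type 1 and 2 with Ncoa5+/- 1 and 4, the 4 livers low in Zhx2, which points to a structure of the samples. This count does not bear on the p53 targets, whose planned list was called with an estimated correlation (adjusted p = 0.0203) and whose list means did not overlap between the 8 livers labelled with the Ncoa5 deletion and the other 8. For double heterozygotes against Ncoa5+/- 2 of 35 did, with 3 genes in the real split and 1054 in the one that follows the mouse tag range, which points to a structure of the samples, and with the tag range as a covariate the real count was 4. For the interaction the splits decide nothing, since the real count was 0 and so each of 100 random assignments calls at least as many (3 in the highest other). The tag range itself went with 405 genes, 188 higher and 217 lower under 4300.

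Lists that were called in none of the 6 comparisons are given with their adjusted p by camera for Ncoa5+/-, Tip30+/- and double heterozygotes against wild type. They were sinusoidal endothelium (0.599, 0.751 and 0.0765), potassium and calcium channels (0.749, 0.231 and 0.89), periportal genes (0.709, 0.0605 and 0.667), secreted hepatocyte proteins (0.797, 0.114 and 0.667), male-biased liver genes (0.298, 0.739 and 0.41), exocrine pancreas (0.796, 0.739 and 0.89, with 3 genes tested) and adipose tissue and muscle (0.891, 0.383 and 0.85, with 2). Female-biased liver genes stood at 0.676, 0.163 and 0.362. Within lists not called, Glul and the complement gene C3 fell in double heterozygotes against wild type (log2 -0.61 and -0.65, adjusted p = 0.0445 and 0.0472). Against Tip30+/- the glutathione transferase genes Gstp1 and Gstp2 rose in double heterozygotes (log2 1.14 and 1.20, 0.0304 and 0.00905) and Glul, the periportal gene Ctsc and the clock gene Hlf fell (log2 -0.68, -0.75 and -0.59, adjusted p = 0.0284, 0.00971 and 0.0324).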
